A study of Homo sapiens with 6 samples.

How the data were processed

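Transcript levels were measured on 6 single-colour arrays of a human transcriptome design, hybridised with RNA from SKOV3 cells, an established human ovarian carcinoma line. Per the labels, 3 arrays carried RNA from cells stably holding the empty hairpin vector and 3 carried RNA from cells stably expressing 1 hairpin against SND1. Per the labels' protocols, cells grew in McCoy's 5A medium with 10% serum and 6 µg of total RNA was used. The label of 1 knockdown array carries an additional number whose meaning is not given, so whether it came from the same clone or culture as the other knockdown arrays is unknown. The hairpin itself, its sequence and any further hairpin were not used here.

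The deposited values are log2 expression per probe set, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes arrays by quantiles and summarises probes) without a version. Array medians of the deposited log2 values ran from 4.13 to 4.19, and all values from 1.85 to 19.9. Of these values, 4457 in 858 probe sets lay above 16, the log2 ceiling of a 16-bit scanner. The deposited scale therefore is not the scanner's own, the variant of RMA behind it is not given in the sources used here, and fold sizes depend on it. The deposited normalization was kept. Scanner files were not used here, so the submitters' background correction and scan batches were not examined, and the labels name no batch. On 23 background control probe sets the mean log2 value ran from 2.38 to 6.28, with a median of 3.11. No probe set has a detection call here. Where the dimmer group's mean of a named gene lay at or below 6.28, its fold is therefore given as at least the brighter group's mean over that level, and where both groups did, only the log2 difference is given, as within the background range. That level is the highest of the 23, and the median of all genes' control means, 5.08, lies below it. The rule therefore puts the control levels of most genes within the background range. It was added after the data were seen.

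Of 70523 probe sets, 23781 carried 1 gene symbol in the platform annotation, 1543 carried several and 45199 had no gene in that table. Symbols were updated through Entrez identifiers for the 21497 probe sets that matched the RefSeq gene table, which changed 306 of them. Probe sets with several symbols name no gene, with 1 exception made after the files were seen: the SND1 probe set is also annotated to SND1-IT1, a transcript from within the SND1 gene, and was kept because SND1 is the target. ZEB2, which shares its probe set with an antisense transcript, is not analysed here for that reason. For the 528 genes with more than 1 probe set, the brightest over all 6 arrays was taken, which gave 22412 genes including SND1. The build behind the array's coordinates is not given in the sources used here, so only the order of genes along chromosomes was used. In comparisons along chromosomes, a gene counted as expressed if its mean over the 6 arrays lay above the median of all deposited values. That median lies below 6.28, so expressed genes in this sense can lie within the background range.

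Differences (SND1 knockdown minus vector control) were fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, without filter or covariate, and p-values were adjusted by Benjamini-Hochberg over all 22412 genes at a threshold of 0.05. Every adjusted p of a gene comes from this 2-sided moderated test with n = 3 arrays per group unless stated. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

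Before the data were examined, 39 gene lists were fixed, covering epithelial and mesenchymal genes, signalling, cell cycle, metabolism, stress, RNA processing, SND1 partners and markers of other cell types. Of their 1019 different members 922 were measured. The result of 1 list is not reported here, though it stays in the counts of lists. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 39 lists. Camera with an estimated correlation, and fry, which asks whether a list's genes move on balance 1 way without comparing them to other genes, were alternatives. The genes named were fixed by rule: SND1, a set of EMT (epithelial-mesenchymal transition) regulators and markers with the acetyltransferase KAT2A, the 10 largest increases and 10 largest decreases past the threshold with no overlap between groups, and up to 4 members of each list with the smallest adjusted p. Genes named outside this rule are identified as chosen after their values were seen.

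The same steps were tested on simulated data, in 20 simulations of the SND1 comparison over 22412 genes with 200 changed genes each. Of the changed genes, 69.3% were called at a log2 size of 0.5, 93.7% at a size of 1 and 99.8% at a size of 2, and 5.2% of calls were false. When the epithelial list alone was moved, it was called and 0 of the 38 other lists were, by camera, and also by fry. Camera with an estimated correlation called the moved list too. Simulated genes varied independently of each other, and the list test used a single simulated data set. It therefore does not show how often lists of correlated genes are called falsely, nor what happens when many genes change. Alternatives covered the replicate number as a block, between-array normalization, filters on dim genes, the choice among probe sets, the variance model, array weights, an ordinary test without shared variance, the list tests and leaving out each array. A fit to genes outside regions that shifted as a whole was added after seeing the data. Figures were drawn with matplotlib 3.10.9.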

Results

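The data comprised 6 transcriptome arrays of SKOV3 ovarian carcinoma cells, 3 from vector control cells and 3 from SND1 knockdown cells. SND1 encodes a staphylococcal nuclease and tudor domain protein that acts in transcription, splicing and RNA turnover. The comparison asked which genes depend on SND1 in these cells, with attention to SNAI2 (SLUG) and the epithelial-mesenchymal transition. Arrays of a group correlated at Pearson's r of 0.9981 to 0.9987 over the 22412 genes, and arrays of different groups at 0.9845 to 0.9861. These correlations are across genes, which are not independent replicates.

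SND1 itself was at least 5.51-fold lower in the knockdown cells. Where the dimmer group lay at or below 6.28, the highest mean of a background control probe set, folds are given as at least the ratio to that level, here and below for SND1 and every other named gene. Its log2 level was 8.74 ± 0.12 (SD, n = 3) in controls and 5.86 ± 0.14 (SD, n = 3) after knockdown, a difference of -2.89 ± 0.09 (SE; limma adjusted p = 1.3e-06), with all 3 knockdown arrays below all 3 controls. This probe set also covers SND1-IT1, so the value is not that of SND1 mRNA alone.

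SNAI2, a transcription factor that represses E-cadherin, fell at least 7.07-fold (log2 difference -3.11 ± 0.16 SE, adjusted p = 9.7e-06). CDH1, the E-cadherin gene, rose 7.22-fold, from 6.47 ± 0.10 (SD, n = 3) in controls (log2 difference 2.85 ± 0.08 SE). CDH2, encoding N-cadherin, fell at least 7.03-fold (log2 difference -4.63) and FN1, encoding fibronectin, at least 4.42-fold (log2 difference -3.95). ZEB1, another repressor of CDH1, fell 2.39-fold. TWIST1, at or below that background level in both groups, fell by 0.34 on the log2 scale (adjusted p = 0.0095), and VIM, the vimentin gene, fell 1.29-fold from a control level of 15.01 ± 0.04 (SD, n = 3). SNAI1, also at or below it in both groups, fell by 0.51 (adjusted p = 0.015), a call that ended when the third knockdown array was left out (adjusted p = 0.055, with a range of 0.009 to 0.085 over all alternatives). The histone acetyltransferase gene KAT2A differed by -0.12 ± 0.08 (SE) on the log2 scale (adjusted p = 0.33), which does not pass the threshold.

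**Figure D1:**
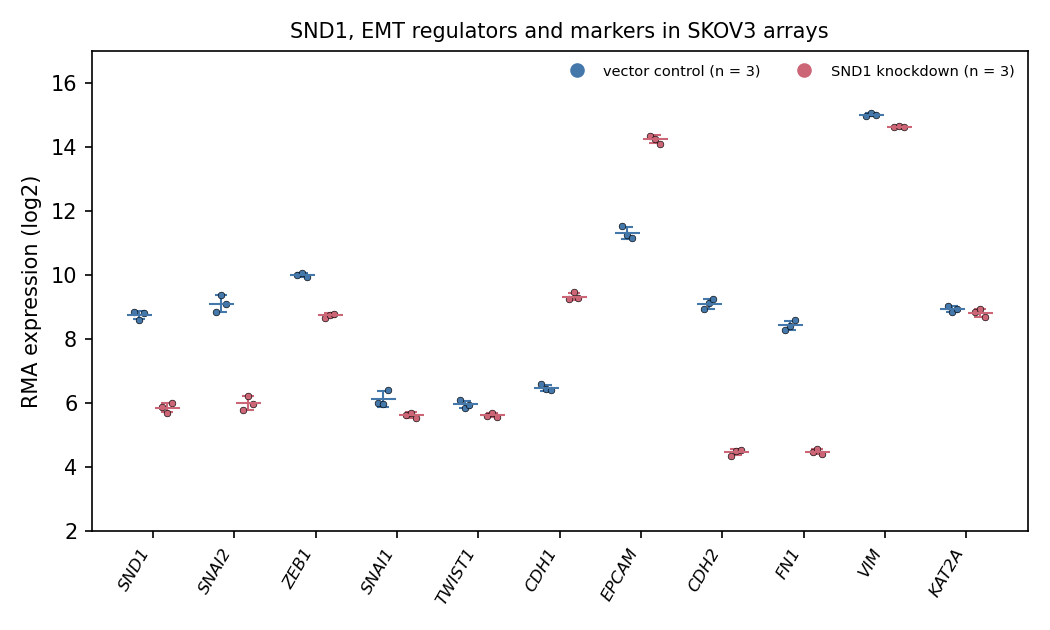
RMA log2 expression (y axis) of SND1, EMT regulators and markers and KAT2A (x axis) in 3 vector control arrays (blue) and 3 SND1 knockdown arrays (red). Points are arrays, horizontal marks are means and error bars are SD. SNAI2, CDH2 and FN1 lie lower and CDH1 and EPCAM higher in every knockdown array than in every control array, whereas the KAT2A groups overlap.

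The fixed lists of epithelial and mesenchymal genes shifted in opposite directions. Of 30 measured epithelial junction and keratin genes 22 rose and 3 fell (median log2 difference 0.58, camera adjusted p = 3.4e-08, and adjusted p = 0.23 with an estimated correlation). CXADR, a tight-junction adhesion receptor, rose at least 94.5-fold, EPCAM, an epithelial adhesion molecule, rose 7.59-fold, and the tight-junction scaffold gene TJP3 rose at least 2.08-fold. The 3 that fell, named after their values were seen, were the keratin genes KRT8 and KRT18 (log2 differences -1.39 and -0.52) and TJP1 (-0.28). Of 28 mesenchymal genes 17 fell and 3 rose (median -0.44, adjusted p = 1.0e-05, and adjusted p = 0.45 with an estimated correlation). FBN1, encoding the microfibril protein fibrillin, fell 10.8-fold, while LUM, encoding the matrix proteoglycan lumican, rose by 1.85 on the log2 scale within the background range. Among 15 EMT transcription factors 10 fell and 1, HMGA2, rose (at least 3.53-fold). That list had a median of -0.23 (adjusted p = 0.012, and adjusted p = 0.26 with an estimated correlation). Of its members that fell, KLF8, SNAI1, TWIST1, PRRX1, GSC and TCF4 lay within the background range in both groups, a listing made after their values were seen. By the same later listing, the mesenchymal genes COL5A2, COL5A1, CDH11, SPARC, POSTN, COL1A1 and COL1A2 fell within that range. The epithelial genes CDH3, CRB3, ST14 and CLDN4 rose within it. Members of the remaining fixed lists were not tallied this way.

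Over all 22412 genes, 3558 rose and 3608 fell after SND1 knockdown, together 32% of genes. By fitted values, at least 2-fold changes were found for 411 genes that rose and 546 that fell. With levels under the highest background mean raised to it, 297 and 351 of these still differed by at least 2-fold. The groups did not overlap for 9774 genes (43.6%), where chance gives 10% with 3 arrays against 3. The median log2 difference over all genes was 0.003.

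Ranked by fitted log2 difference, the largest increase after CXADR was that of DPP4, encoding a cell-surface dipeptidyl peptidase, at 61.2-fold (5.94 ± 0.15 SE). FAM83B rose 24.9-fold, the epithelial transcription factor gene TFCP2L1 at least 10-fold and KLHL14 at least 5.23-fold. TMPRSS4, encoding a membrane serine protease, rose at least 3.82-fold, ARL14 at least 3.67-fold, GPRIN3 at least 3.61-fold and IL1R2, encoding the decoy receptor for interleukin-1, at least 3.04-fold, and CFAP47 rose 10.3-fold. CDH6, encoding a cadherin of kidney and ovarian tumours, showed the largest fitted decrease, at least 169-fold (log2 difference -8.94 ± 0.16 SE, from 13.68 ± 0.32 SD in controls). The receptor tyrosine kinase gene KIT fell at least 23.7-fold, DPYSL3 at least 66-fold and THBS1, encoding the matrix protein thrombospondin-1, 84.9-fold. AMTN fell 80.3-fold and the long noncoding RNA UCA1 50.3-fold, OPRPN at least 14.8-fold, TOX at least 12.9-fold and the ephrin receptor gene EPHA4 at least 7.8-fold. Adjusted p was at most 3.2e-06 for all 20 of these genes, CDH2 included.

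**Figure D2:**
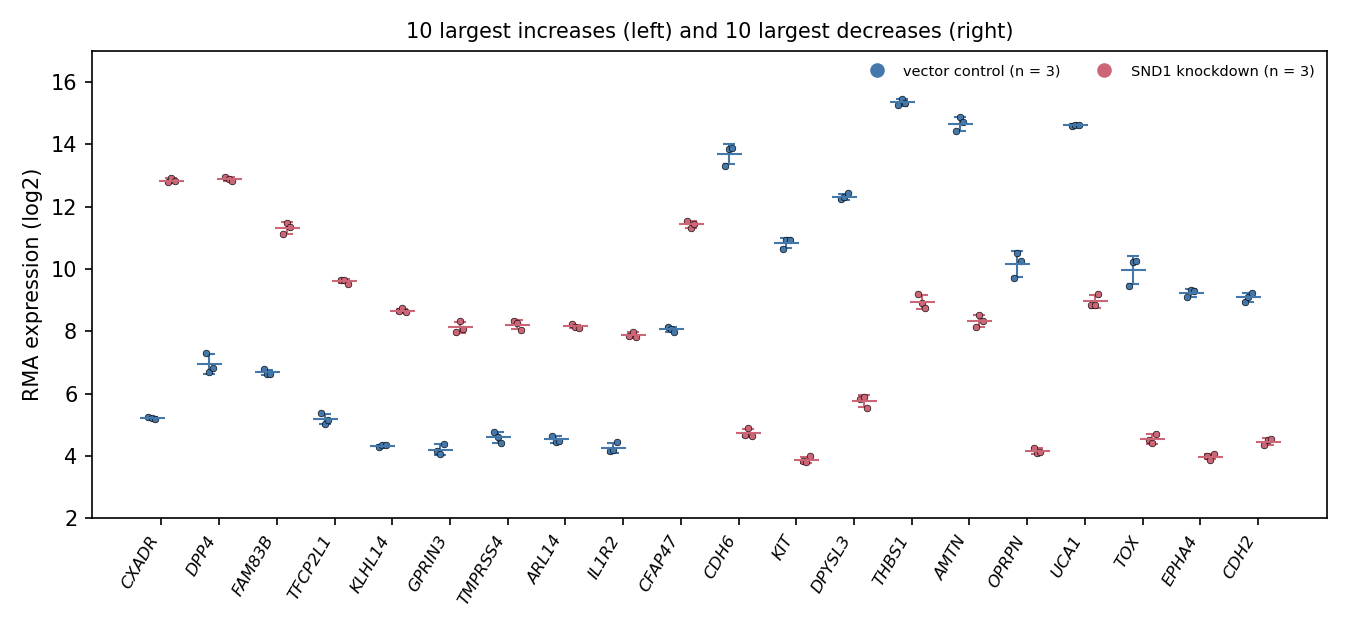
RMA log2 expression (y axis) of the 10 genes with the largest fitted increases and the 10 with the largest fitted decreases (x axis) in 3 vector control arrays (blue) and 3 SND1 knockdown arrays (red). Points are arrays, horizontal marks are means and error bars are SD. CXADR and CDH6 show the widest gaps, with log2 differences of 7.62 and -8.94.

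Targets of the transcriptional coactivators YAP and TAZ were the list with the smallest p. Of 23 measured, 18 fell and 2 rose (median -0.78, adjusted p = 1.5e-08, and adjusted p = 0.23 with an estimated correlation). RBMS3 fell at least 2.3-fold, the receptor tyrosine kinase gene AXL 3.48-fold and CRIM1 3.25-fold, whereas NT5E, encoding the ecto-enzyme CD73, rose 8.18-fold.

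Of 34 TGF-beta and SMAD genes 16 fell and 5 rose (median -0.16, adjusted p = 0.005, and adjusted p = 0.44 with an estimated correlation). The ligand genes INHBA and TGFB2 fell at least 1.85-fold and at least 1.4-fold, TGFB1 fell 2.52-fold and ID3 fell at least 1.54-fold. Of 30 matrix protease and inhibitor genes 16 fell and 4 rose (median -0.31, adjusted p = 5.5e-05, and adjusted p = 0.26 with an estimated correlation). ADAMTS1 fell 12.9-fold, MMP16 at least 2.31-fold, the collagenase gene MMP1 5.56-fold and the inhibitor gene TIMP1 at least 1.62-fold. MMP1 and the apoptosis inhibitor gene BIRC2 lie in a run of neighbouring genes on chromosome 11 whose median was -0.59.

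Cholesterol synthesis and uptake genes fell together, 16 of 20 measured, with 1 higher (median -0.62, adjusted p = 3.8e-08, and adjusted p = 0.44 with an estimated correlation). SC5D fell 5.93-fold, STARD4 at least 2.24-fold, CYP51A1 2.78-fold and SREBF2, encoding the transcription factor that drives the pathway, 1.57-fold. Of 22 glycolysis genes 9 fell and 2 rose (median -0.11, adjusted p = 0.013, and adjusted p = 0.56 with an estimated correlation). The hexokinase gene HK1 fell 2.06-fold, HK2 fell by 0.87 on the log2 scale within the background range, and PFKP rose 1.61-fold. Of 24 hypoxia-induced genes 13 fell and 4 rose (median -0.25, adjusted p = 0.01, and adjusted p = 0.51 with an estimated correlation). BNIP3 fell 7.08-fold and NDRG1 2.55-fold, while CA12, a carbonic anhydrase gene, rose 4.3-fold.

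Mitotic genes were lower, with 22 of 36 falling and 2 rising (median -0.26, adjusted p = 1.5e-06, and adjusted p = 0.45 with an estimated correlation). DLGAP5 fell 2.05-fold, CDC20 1.52-fold and ANLN 1.51-fold, and CDC25B rose 1.58-fold. DLGAP5 lies on chromosome 14, whose expressed genes had a median log2 difference of -0.27. Of 31 NF-kB target, cytokine and chemokine genes 13 fell and 3 rose (median -0.19, adjusted p = 0.0051, and adjusted p = 0.26 with an estimated correlation). The chemokine gene CXCL1 fell at least 2.85-fold, CXCL2 fell by 0.80 on the log2 scale within the background range, and IL1A rose at least 1.34-fold.

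Genes of the MHC class I antigen presentation list rose, 14 of 21, with 1 lower (median 0.72, adjusted p = 2.9e-06, and adjusted p = 0.26 with an estimated correlation). As fixed, the list also holds HLA-DRA, HLA-DMA, CD74 and CIITA, which belong to class II presentation. Its counts and median are therefore not those of class I genes alone. The peptide transporter gene TAP1 rose 3.36-fold, and all 8 of its probe sets, most of them for alternative haplotypes, rose. HLA-B rose 2.7-fold and HLA-G at least 1.49-fold, though the probes of these near-identical genes cannot be assumed to separate them. NLRC5, encoding the activator of class I genes, rose at least 1.32-fold. It lies in a run of chromosome 16 genes whose median was -0.88. That run includes metallothionein genes, many of which fell, so the median does not show a fall of the region apart from them. Of 22 mitochondrial respiratory chain genes 7 rose and 1 fell (median 0.08, adjusted p = 0.029, and adjusted p = 0.6 with an estimated correlation). COX5B rose 2.5-fold, NDUFS1 1.54-fold and NDUFB5 1.39-fold, and NDUFV1 fell 1.38-fold. This list lost its call without the first control array (adjusted p = 0.059) or the second knockdown array (adjusted p = 0.093), after renewed quantile normalization (0.055) and among genes above the median of all probe sets (0.09), in a range of 0.011 to 0.6 over all alternatives.

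**Figure D3:**
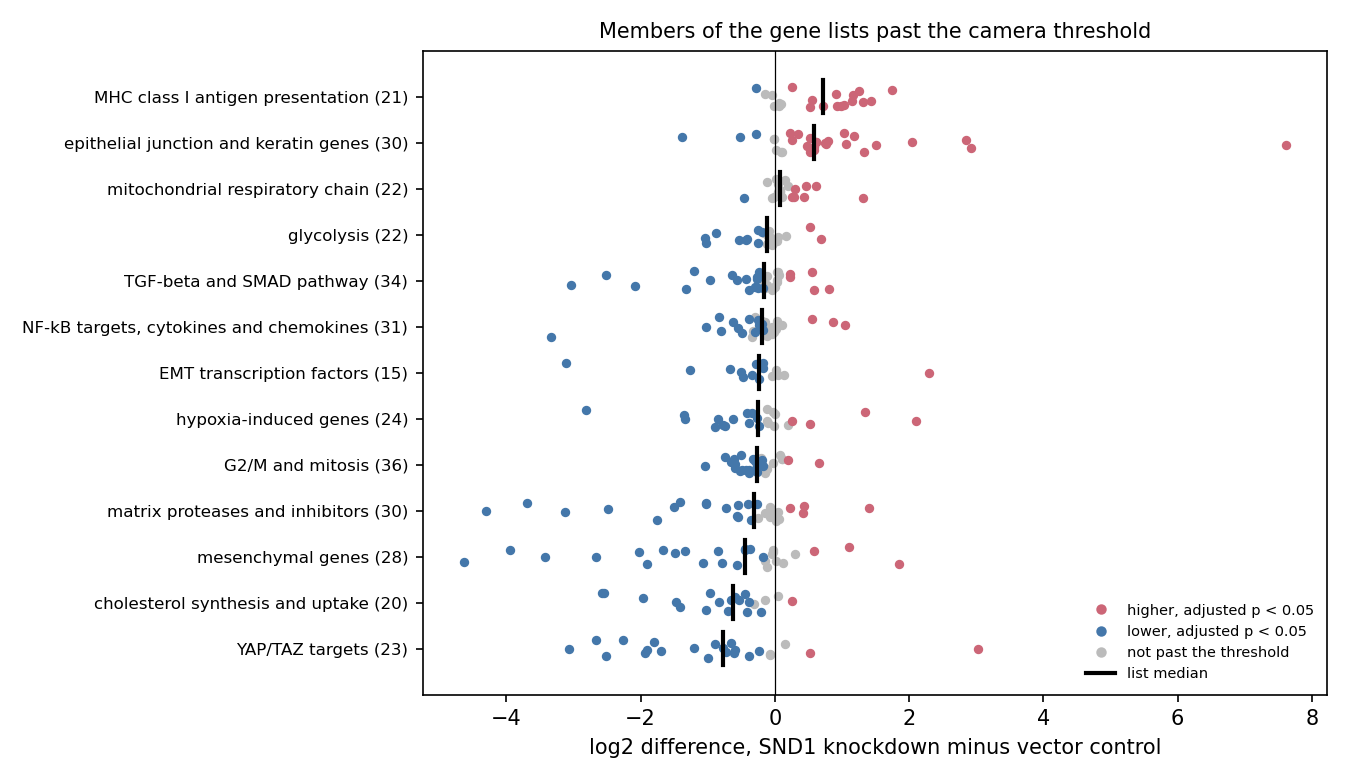
Log2 difference of SND1 knockdown minus vector control (x axis) for each measured member of 13 lists past the camera threshold (y axis, with the number measured in brackets). Points are genes, red where higher and blue where lower past the threshold, grey where not past it, and black bars are list medians. The YAP/TAZ target median lies at -0.78 and the MHC class I median at 0.72.

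With camera, 14 of the 39 lists passed, 3 higher and 11 lower. None of the 14 calls held with an estimated correlation, where camera called 0 lists and 6 had an unadjusted p under 0.05, the lowest at 0.0082. Fry called 27 lists, 7 higher and 20 lower. Of the lists that camera did not call, fry called 12 in camera's direction and 1 in the other. Counted against a threshold adjusted over the list alone, 28 mitotic genes rather than 22 were lower, 18 cholesterol genes rather than 16 and 16 NF-kB genes rather than 13. For mesenchymal genes the counts were 18 lower and 4 higher, for TGF-beta genes 17 lower, for MHC class I genes 2 lower, for hypoxia genes 5 higher and for glycolysis 3 higher. The remaining counts of the lists described were the same when adjusted over the list alone.

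The other 25 lists did not pass camera, although in most of them some members rose and others fell. Over all genes 32% were past the threshold. Of 35 receptor tyrosine kinase, ligand and ERK feedback genes 13 rose and 12 fell (median 0.04, adjusted p = 0.82; 14 and 14 adjusted over the list alone). Camera placed this list higher and fry lower (fry adjusted p = 0.022). SPRY2, an inhibitor of ERK signalling, rose 3.49-fold. NRG1 fell 2.09-fold on its brightest probe set, whereas its other probe sets, at -0.09 and -0.34 on the log2 scale, did not pass. Of 26 integrin and focal adhesion genes 8 rose and 13 fell (median -0.14, adjusted p = 0.22; 8 and 13 adjusted over the list alone). ITGB6 rose 5.75-fold and ITGB4 3.64-fold, while ACTN1 fell 1.88-fold and ITGA4 fell by 1.53 on the log2 scale within the background range. Basement membrane genes numbered 2 higher and 6 lower of 14 (median -0.09, adjusted p = 0.17; 2 and 6 adjusted over the list alone), with LAMB1 rising 2.64-fold and NID2 falling 3.67-fold. ACTN1 and NID2 lie on chromosome 14. DPP4, ITGB6 and the interferon-induced RNA sensor gene IFIH1 lie in a run of chromosome 2 genes whose median was 0.84.

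Of 35 Wnt pathway genes 7 rose and 13 fell (median -0.03, adjusted p = 0.32; 8 and 13 adjusted over the list alone). The Wnt antagonist genes DKK1 and SFRP1 fell 7.01-fold and at least 4.97-fold, WNT5A fell by 1.20 on the log2 scale within the background range and LGR4 rose 2.48-fold. Of 18 Notch genes 7 rose and 3 fell (median 0.05, adjusted p = 0.47; 7 and 3 adjusted over the list alone). The ligand gene JAG1 rose 1.79-fold and HES1 1.58-fold, and HEY2 fell by 1.32 on the log2 scale within the background range. Of 39 interferon-stimulated genes 12 rose and 6 fell (median 0.02, adjusted p = 0.41; 13 and 6 adjusted over the list alone). IFIH1 rose at least 1.71-fold and USP18 at least 1.17-fold, whereas IFI27, on chromosome 14, fell at least 1.8-fold.

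In the G1/S and replication list 10 of 38 rose and 13 fell (median -0.03, mean 0.01, camera direction down, adjusted p = 0.9; 13 and 14 adjusted over the list alone). The kinase gene CDK6 fell at least 4.04-fold and CDK4 1.79-fold, while the cyclin genes CCND1 and CCNE1 rose 3.2-fold and 2.28-fold. Of 23 p53 targets 8 rose and 4 fell (median 0.12, adjusted p = 0.22; 8 and 4 adjusted over the list alone), with GDF15 rising at least 1.75-fold and PLK2 falling 9.17-fold. Of 28 apoptosis regulators 9 rose and 8 fell (median 0.02, mean -0.01, camera direction up, adjusted p = 0.82; 11 and 8 adjusted over the list alone). CASP8 rose 1.72-fold and CASP10 at least 1.29-fold, BIRC2 fell 2.08-fold, and BCL2 fell by 1.26 on the log2 scale within the background range. Of 24 heat shock and immediate early genes 5 rose and 9 fell (median -0.14, adjusted p = 0.063; 5 and 10 adjusted over the list alone), with KLF6 falling 2.42-fold and JUN at least 2.08-fold. Without the second knockdown array this list was called (adjusted p = 0.038, with a range of 0.0043 to 0.6 over all alternatives). Of 35 unfolded protein and integrated stress response genes 7 rose and 12 fell (median -0.11, adjusted p = 0.47; 7 and 15 adjusted over the list alone), and the chaperone gene DNAJC3 rose 2.57-fold.

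Lists of SND1's known partners and functions did not pass camera. Of these lists fry called RISC and microRNA processing lower (fry adjusted p = 0.0066), stress granules higher (0.025) and ribosomal proteins lower (0.033). Of 17 genes for SND1-associated proteins 5 rose and 6 fell (median 0.02, mean 0.01, camera direction down, adjusted p = 0.9; 6 and 7 adjusted over the list alone). STAT6 rose 1.45-fold, STAT5B fell 1.31-fold and STAT5A, within the background range, fell by 0.36 on the log2 scale. Of 16 RISC and microRNA processing genes 2 rose and 4 fell (median -0.04, adjusted p = 0.64; 2 and 4 adjusted over the list alone). DICER1, encoding the RNase that matures microRNAs, rose 1.64-fold although it lies on chromosome 14, and TNRC6C fell at least 1.5-fold. Of 19 stress granule genes 8 rose and 5 fell (median 0.11, adjusted p = 0.4; 8 and 5 adjusted over the list alone). Of 29 splicing factor genes 5 rose and 7 fell (median -0.04, adjusted p = 0.72; 5 and 7 adjusted over the list alone), with SRSF7 rising 1.47-fold in a run of chromosome 2 genes with a median of 0.49. Of 26 histone acetyltransferase and deacetylase genes 8 rose and 6 fell (median 0.01, adjusted p = 0.82; 9 and 7 adjusted over the list alone), and HDAC4 rose by 0.71 on the log2 scale within the background range. Of 20 ribosomal protein genes 0 rose and 6 fell (median -0.08, adjusted p = 0.11; 0 and 7 adjusted over the list alone). Of 9 histone genes 1 rose and 0 fell (median -0.16, adjusted p = 0.7; 1 and 0 adjusted over the list alone).

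Of 31 fatty acid and triglyceride genes 10 rose and 12 fell (median -0.06, adjusted p = 0.7; 10 and 12 adjusted over the list alone). The nuclear receptor gene PPARG rose 2.36-fold and ANGPTL4, within the background range, rose by 1.35 on the log2 scale, while ACSL4 fell 2.98-fold and FABP5 at least 1.85-fold. Of 25 drug efflux and xenobiotic defence genes 6 rose and 10 fell (median -0.04, adjusted p = 0.72; 7 and 11 adjusted over the list alone). The efflux transporter genes ABCG2 and ABCC4 rose at least 1.06-fold and 2.4-fold, and ME1 fell 3.47-fold. Of 21 Mullerian and ovarian epithelial markers 4 rose and 5 fell (median -0.03, adjusted p = 0.72; 4 and 5 adjusted over the list alone). The tumour antigen genes MUC16 and FOLR1 fell at least 1.19-fold and 3.5-fold, BCAM fell 3.97-fold and the oestrogen receptor gene ESR1 rose 2.03-fold. Of 16 stem cell-associated genes, EPCAM and KIT among them, 4 rose and 4 fell (median -0.04, adjusted p = 0.89; 5 and 4 adjusted over the list alone).

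Lists of markers of other cell types did not pass camera, though fry called the fibroblast list higher (fry adjusted p = 0.00012). Of 24 leukocyte markers 2 rose and 0 fell (median -0.01, mean 0.06, camera direction up, adjusted p = 0.72; 2 and 0 adjusted over the list alone). LAPTM5 rose by 1.31 on the log2 scale within the background range. Of 16 endothelial markers 1 rose and 1 fell (median 0.02, camera direction up and fry direction down, adjusted p = 0.89; 1 and 1 adjusted over the list alone). Of 15 fibroblast markers 3 rose and 4 fell (median -0.03, mean 0.50, camera direction up, adjusted p = 0.77; 3 and 4 adjusted over the list alone), with 8 of the 15 also among the mesenchymal genes. The list holds DPP4, with a log2 difference of 5.94, and LUM, at 1.85 within the background range. Such members raise its mean above its median, and whether the fry call rests on them was not tested. MFAP5 rose 2.18-fold and POSTN, within the background range, fell by 0.79 on the log2 scale.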

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

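Tests of fibroblasts, of genes matched in level or in length and spacing, and of blocks along chromosome 14 were chosen only after the results they bear on had been seen. Probe sets that name no gene were outside every comparison of the report. Of 42204 such transcript probe sets, 1609 were higher and 1137 lower after SND1 knockdown by limma, and at least 2-fold changes numbered 341 higher and 333 lower.

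The broadest pattern was the number of genes changed at least 2-fold, 957 by fitted values, of which 448 had their dimmer group at or below the highest background mean. A copy-number difference moves neighbouring genes together, but the 10 nearest expressed neighbours on each side of these genes had a median log2 difference of 0.026 in the gene's own direction (95% bootstrap interval 0.014 to 0.041, 937 genes). Over the set as a whole, the neighbours thus stayed well under the 0.3 that the test set for gained or lost copies. Still, 9.4% of the genes had neighbours shifted by at least 0.3 the same way, against 2.2% the opposite way. Changes of at least 2-fold exceed that 0.3, so a small median was likely beforehand. Smaller regional shifts are not weighed by it, and the neighbours can include genes within the background range. Whether 1 group came from another cell line cannot be told apart from the knockdown, since among the marker genes of SKOV3 chosen for the test only CDKN2A, deleted in that line, had a probe set of its own (difference 0.07, at 3.73 in controls and 3.80 after knockdown). An effect of SND1 loss, an effect of this hairpin on other transcripts and drift between separately selected cells stay open and may all contribute, since 1 hairpin was used and the clones behind the arrays are not given.

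The 474 expressed genes of chromosome 14 were lower as a block, with a median of -0.27, and 78.1% of them lay below 0 (95% Wilson interval 74.1 to 81.6) against 49.1% of all expressed genes. Expressed means here only a mean level above the median of all deposited values, so genes within the background range can be included. The largest chromosome median in 100 shuffled gene orders was 0.07, which 6 of 23 chromosomes exceeded in size, the others being 13 (0.18), 6 (0.10), 2 (0.09), 19 (-0.09) and 22 (-0.08), and the chromosome 14 medians were -0.25, -0.26 and -0.27 in the knockdown arrays against -0.01 to 0.01 in controls. Genes of other chromosomes matched to those of chromosome 14 in gene length and spacing had a median of 0.02 (95% bootstrap interval 0.01 to 0.04), which argues against gene density or length as the whole cause; base composition was not tested, and removing the linear trend with both (0.17% of the variance, median then -0.27) changed little on any chromosome examined. A copy-number difference may have arisen during selection of the cells, and it stays open: 20 of 23 consecutive blocks of 20 genes (87%, 95% Wilson interval 67.9 to 95.5) had a median below -0.1, an interval whose lower end missed the 70% set for a change along the whole chromosome. No DNA measurement and no size expected of a lost copy was set against these values.

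The rise of epithelial genes with the fall of mesenchymal genes was weighed against fibroblasts in the control cultures. The fibroblast list had a median of -0.03 (95% bootstrap interval -0.17 to 0.30), above the -0.44 of the mesenchymal list, and COL1A1, COL1A2, DCN and LUM lay at percentiles 46.9, 36.5, 21.2 and 37.8 of control levels, which argues against that source. Of the 15 fibroblast list members 8 are also mesenchymal list members, so these medians are not independent. In an established cell line fibroblasts were unlikely beforehand, so the test adds little. In 21 pairs of an epithelial gene with the mesenchymal gene nearest in level, 13 mesenchymal genes being used, the epithelial gene changed more toward higher values in all 21 (median paired difference 1.90, 95% bootstrap interval 1.14 to 3.25). The opposite directions of both lists were already known, so the sign was likely beforehand. That it held at matched level argues against a difference that depends on intensity alone, for these pairs only. Of 30 epithelial genes measured, the rest had no mesenchymal gene within 0.5 in level. Pairs that reuse a gene are not independent, so the interval is likely too narrow. A loss of mesenchymal state with SND1 and SNAI2 remains a hypothesis, found and tested on the same arrays, and a difference between the groups unrelated to SND1 could give the same values.

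The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For each count of genes 1 of the 10 splits, the real one, reached the observed value: the real split gave 3558 higher and 3608 lower genes, with 411 and 546 at least 2-fold, and the highest of the other splits gave 0 for each. For lists called by camera the real split gave 14 and the highest of the other splits 11. Every other split puts arrays of both groups on each side, so the difference between the groups adds to the spread within each side. A count of 0 genes was therefore close to fixed in advance, and the 11 lists may carry part of the same difference. These splits do not measure chance, and no conclusion is drawn from them.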

How the results depend on the processing

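The fit to genes outside shifted regions was chosen after seeing the data. The number of lists called by camera, 14, became 0 with an estimated correlation and 27 with fry. These tests differ by construction, since the first estimates the correlation from the data and the second does not compare lists with other genes. The estimated correlations were not examined, so the loss of calls cannot be put down to correlation among genes rather than to the small number of arrays. The receptor tyrosine kinase list changed direction, from higher by camera to lower by fry (adjusted p = 0.022, against 0.82 in the main test and a range of 0.022 to 0.91); the cause was not tested. With the replicate block, 3093 genes were higher and 3139 lower, 411 and 546 of them at least 2-fold, SND1 was at -2.89, and 15 lists were called, heat shock genes being added (adjusted p = 0.049). Same-numbered arrays did not deviate together (correlations -0.02, -0.04 and -0.06), so the numbers do not pair them. Leaving out each array gave 2909 to 3501 higher and 2957 to 3384 lower genes, 390 to 434 and 531 to 566 at least 2-fold, 13 to 14 lists and SND1 at -2.96 to -2.81. All other alternatives left these counts within 1.5 times the main value. Outside chromosome 14 and the shifted runs of genes, 3332 rose, 3229 fell and 14 lists were called. Some single calls moved: SNAI1 (adjusted p = 0.085), RPS19 (0.067) and RPL18 (0.061) were lost with the ordinary test per gene. That test, the robust variance model and the fit per probe set were not run for lists. Signal over background limits genes near the background level, and 3 arrays per group limit small changes.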

Other observations

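Families sharing a symbol stem, neighbouring runs of genes and the genes named here were chosen only after the data were seen. Of 261 families of at least 10 genes, 6 passed camera, and with an estimated correlation their adjusted p was 0.99. Pregnancy-specific glycoprotein genes fell, 8 of 10 with 0 higher (median -0.81, adjusted p = 3.5e-05), but 8 of the 10 lay within the background range in both groups, PSG1 (log2 difference -2.56) among them, and PSG5 fell at least 1.04-fold. Of those 8 within the background range, 6 were past the threshold. Clustered protocadherin beta genes fell, 11 of 18 with 0 higher (median -0.52, adjusted p = 0.0038), with PCDHB13 falling 2.82-fold and PCDHB14 at least 2.56-fold, and 10 of the 18 lay within the background range in both groups. Of those 10, 4 were past the threshold. The run of genes from PCDHB6 to PCDHGB7 on chromosome 5 is itself among the shifted windows (median -0.58, 12 lower and 1 higher). HSPA chaperone genes rose, 7 of 13 with 0 lower (median 0.30, adjusted p = 0.02), as did DNAJC cochaperone genes, 14 of 28 with 1 lower (median 0.16, adjusted p = 0.02), HLA genes, 10 of 27 with 0 lower (median 0.08, adjusted p = 0.012) and GOLGA genes, 9 of 31 with 0 lower (median 0.13, adjusted p = 0.036). Some members of the PSG, PCDHB, HLA and GOLGA stems are closely similar copies, so probes shared between them leave the number of genes moved uncertain. Within the background range in both groups lay 19 of the 27 HLA, 19 of the 31 GOLGA, 12 of the 28 DNAJC and 4 of the 13 HSPA genes. Of these, 2, 2, 5 and 0 were past the threshold. Under renewed quantile normalization and median centring all 6 family medians had the same sign, the smallest being 0.08 for HLA genes. After quantile normalization 9 rather than 14 of the 28 DNAJC genes were higher.

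The receptor tyrosine kinase, ligand and ERK feedback list did not pass camera, and no part of it was tested separately. Among its members SPRY2 rose 3.49-fold, PHLDA1 2.13-fold and SPRED2 1.51-fold, and SPRY1 rose at least 2.78-fold, ETV5 at least 2.71-fold, ETV4 at least 2.15-fold, SPRY4 at least 1.79-fold, DUSP6 at least 1.71-fold and DUSP5 at least 1.39-fold. SPRED1 differed by 0.04 on the log2 scale (adjusted p = 0.59), and DUSP4, within the background range, was lower by 0.42. Receptor genes went both ways, with KIT falling at least 23.7-fold, AXL 3.48-fold and EGFR 1.62-fold, and MET rising 1.28-fold and DDR1 at least 1.28-fold. FGFR3, within the background range, rose by 0.68 on the log2 scale.

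Of 16 measured metallothionein genes and pseudogenes, whose proteins bind zinc and copper, 14 were lower and 0 higher (median -1.09), with MT2A falling 8.95-fold and MT1X 5.35-fold, and 11 of the 16 lay within the background range in both groups. Of those 11, 9 were past the threshold. The metallothionein group was tallied after its values were seen and was not tested as a list, and some of its members are closely similar copies. Many lie on chromosome 16, where the run of genes from CES1 to MT1X had a median of -0.88, with 12 of 20 lower and 5 higher. That run includes metallothionein genes themselves, so its median is not separate evidence of a regional shift. YAP1, the gene of the coactivator YAP, was 1.94-fold lower (log2 difference -0.95 ± 0.05 SE, adjusted p = 1.1e-05), and the 20 genes from YAP1 to ACAT1 on chromosome 11 had a median of -0.57, with 13 lower and 0 higher. Of 2708 windows of 20 neighbouring expressed genes, 34 lay beyond the 95th percentile of the largest shuffled window (0.46), 20 higher and 14 lower. Windows started every 5 genes and overlap, so 34 is not a number of separate regions. Genes of chromosome 13 were higher, with a median of 0.18. Of the 957 genes changed at least 2-fold by fitted values, 116 (12.1%) lay on chromosome 14 or in such a window.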
